A study of Mus musculus with 28 samples.

How the data were processed

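RNA from endothelial (CD31) and mural (PDGFRb) cells of mouse brains was read in 28 libraries of 6 groups, the 2 sorts in breast BrM, lung BrM and non-tumor brain. Per the labels, libraries were made with a SMART-Seq low-input kit and Nextera XT, which keep no strand, so antisense transcripts cannot be told from sense ones. Amplified reads carried no molecular barcodes, so intervals and floors from counts cover counting error only, while p-values measure the spread between mice.

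The 5 deposited tables hold 3 kinds of values. The submitters' processing notes name STAR 2.7.9a, RSEM 1.3.3, edgeR 3.36.0, limma 3.50.3 and the mouse genome build mm10, without their order or the annotation release. The expected counts are the authors' estimated read counts per gene, with fractions and no scaling, and cover 53647 gene IDs. The deposited log2 values, 1 table per sort with 18665 genes in all libraries, are the authors' log2 of counts per scaled library size. At least 99.98% of their genes lay within 0.01 of values recomputed from the counts in that form. The FPKM values, fragments scaled by gene length and library size, were deposited by the authors for the same number of genes. The filter that left these genes is not stated. No per-sample column lacked a sample. Of the gene IDs, 52093 matched a symbol of the reference, and rows without one held 0.182% to 1.57% of the counts. Only 35 IDs carried the reference's version, so no coordinates are given.

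Groups were read from the sample titles, and the mouse number in the title was taken as the replicate. For mouse 54135 title and cell type label name opposite sorts in both libraries, which were grouped by title, the reading that their Pecam1 and Pdgfrb levels fit. 2 lung labels name 2 mouse numbers each and were kept as 1 replicate each. All 28 libraries were used. Pairing rests on the same mouse number in both sorts. In 13 mice with both sorts, 2 pairs had a correlation of deviations from the group means above 0.1 (range -0.09 to 0.27, median -0.02), and 5 correlated best with their own partner, so the comparisons between sorts were made without a block and repeated with it.

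Expected counts were rounded, genes were kept by edgeR's filterByExpr, and libraries were scaled by TMM. Each sort was fitted with its 3 groups, and the comparisons between sorts with all 6 groups, using edgeR 4.0.16's quasi-likelihood test with robust dispersions in R 4.3.3. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. BrM against non-tumor is the mean of the breast and lung effects. CPM of the sort genes rest on raw totals, and CPM of other genes on TMM-scaled totals. Library totals ranged from 13.6 M to 20.8 M counts in CD31 breast, 12.9 M to 18.1 M in CD31 lung, 17 M to 20.8 M in CD31 non-tumor, 7.11 M to 23.9 M in PDGFRb breast, 13.4 M to 20.4 M in PDGFRb lung and 14.9 M to 22.5 M in PDGFRb non-tumor libraries. Mitochondrial genes held 0.998% to 3.34% of counts. The closest replicate pair still differed by 16.4 times the counting error (chi-square per degree of freedom).

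36 gene lists, written with the grouping, tests, named-gene rule and most alternatives before the data were examined, were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the lists. 4 list symbols had no match. Members were also adjusted over the list alone.

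Named genes are the sort genes, 8 CD31 and 7 PDGFRb genes set in advance, and the 5 largest rises and 5 largest falls among called genes with a mean log2 CPM of at least 3 and no overlap between the libraries compared. Gene models, mitochondrial genes, receptor segments and pseudogenes were left out. Per list described, up to 4 called members with the largest changes were named, or the member with the smallest p where none passed, and fewer where others moved with 1 library. Krt8 was shown beside the sort genes after its values were seen. 1 gene that met the rule is not reported here, and the next was taken. A gene without counts in a group is given as at least N-fold against 3 counts over the group, and a gene with 1 to 3 counts as a ratio with its 95% counting interval. Members of families of near copies are reported as uncertain.

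The test was tried on data simulated with the replicate spread of each sort and 50 changed genes per fold. In the CD31 design it recovered 32%, 78%, 92% and 88% of genes changed 2, 4, 16 and 64 times, and called 0.03% of unchanged genes. In the PDGFRb design it recovered 6%, 18%, 70% and 92%, and called 0.019%. These rates of false calls hold for few changed genes only.

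Alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no filter, a filter at 1 CPM, limma-trend on the deposited log2 values and on log2 FPKM with pseudocounts of 1 and 0.1 or a mean FPKM of at least 1, an absolute log2 change of at least 1, leaving out each library, mouse 54135 or the lung mice with 2 numbers, mouse 54135 by its cell type label, fits of only the groups compared or of all libraries, and the mouse as a block. Relative to TMM, RLE moved the median log2 change of all genes by -0.12 in the PDGFRb comparisons with non-tumor brain and in the difference between sorts, and by 0.17 in the comparison of sorts, where upper-quartile scaling moved it by 0.12. Added after the data were seen were the date in the column names, Y-linked reads, Xist, the lung PDGFRb libraries with Pdgfrb under 50 CPM and carried-over cancer RNA. For the latter, each mouse's ratio of summed epithelial CPM in its CD31 and PDGFRb libraries was multiplied by a gene's PDGFRb level. This assumes carried-over RNA of that library's composition. The share is in percent of the CD31 level, or of the rise where stated. It is no limit, as epithelial Cldn4 and Apob came to 59% and 62.6%. Mural RNA can raise it, as all 6 pericyte rises reached 50%.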

Results

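The series holds RNA-seq libraries of vascular cells sorted from mouse brains with and without experimental brain metastasis (BrM). Metastases were grown from PyMT-BrM3 cells, a breast cancer line, or from Sv2T3-BrM1 cells, a lung cancer line, injected into the heart of mice whose PDGFRb-expressing mural cells carry the red reporter tdTomato. Endothelial cells were collected as CD31-positive cells free of CD45, CD11b and EPCAM, and mural cells as tdTomato-positive cells. The CD31 sort gave 5 libraries from breast BrM, 5 from lung BrM and 5 from non-tumor brain, and the PDGFRb sort gave 4, 4 and 5. The 28 libraries came from 15 mice or pools of mice, of which 13 gave both sorts. Totals ranged from 7.11 M to 23.9 M counts per library. A gene with 3 counts in a library stood at 0.125 to 0.422 CPM (counts scaled to library size). The PDGFRb breast library of mouse 51950 had the fewest counts, 7.11 M, and the fewest genes detected, 9174, against 12601 to 22752 in the other 27 libraries.

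The genes behind the gates were read first in every library. Pecam1, which encodes CD31, stood at 1306 ± 29.9 CPM in the CD31 sort of non-tumor brain, 828 ± 133 in breast BrM and 933 ± 255 in lung BrM (mean ± SD, n = 5 each), and at no more than 13.1 CPM in any PDGFRb library. Pdgfrb reached 1291 ± 349 CPM (n = 5) in the PDGFRb sort of non-tumor brain and 775 ± 360 (n = 4) in breast BrM, and its highest value in a CD31 library was 14 CPM. In the PDGFRb sort of lung BrM, Pdgfrb stood at 446 CPM in mouse 51435 and at 36.4, 38.4 and 43.8 CPM in the other 3 libraries. Ptprc, which encodes CD45, did not exceed 16.4 CPM and Itgam, which encodes CD11b, did not exceed 3.3 CPM in any library. Epcam, an epithelial adhesion molecule, was at 115 ± 167 CPM in the CD31 sort of breast BrM, 8.22 ± 16.9 in lung BrM and 0.202 ± 0.324 in non-tumor brain (n = 5 each). In the PDGFRb sort, for which the labels name no EPCAM gate, it was at 158 ± 99.7 CPM in breast BrM (n = 4), 16.2 ± 13 in lung BrM (n = 4) and 1.49 ± 2.65 in non-tumor brain (n = 5). Krt8, an epithelial keratin, was at 3173 ± 757 CPM (n = 4) in the PDGFRb sort of lung BrM, 673 ± 383 (n = 4) in breast BrM and 3.85 ± 3.23 (n = 5) in non-tumor brain. In the CD31 sort Krt8 was at 306 ± 321 CPM in lung BrM, 282 ± 370 in breast BrM and 0.461 ± 0.461 in non-tumor brain (n = 5 each). Epithelial RNA was thus present in both sorts of BrM.

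**Figure D1:**
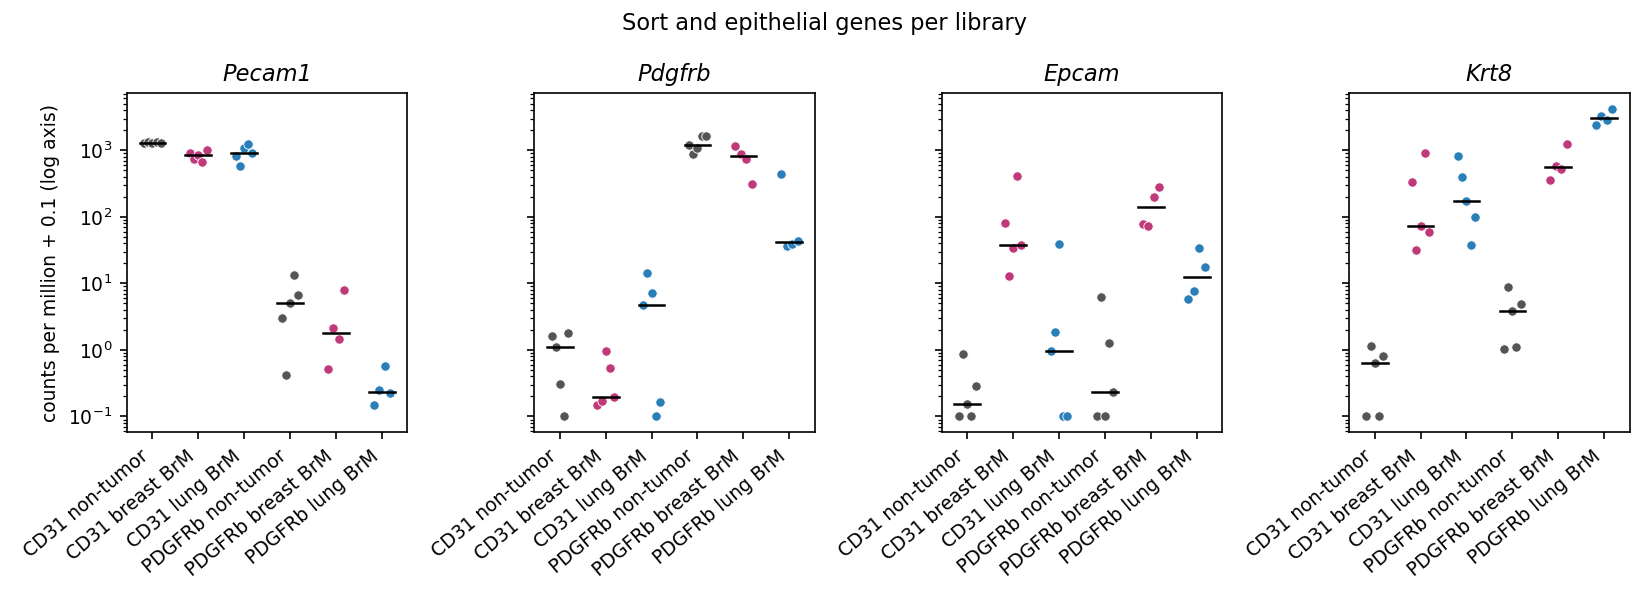
CPM + 0.1 of Pecam1, Pdgfrb, Epcam and Krt8 on a logarithmic axis in each library, with libraries grouped by sort and by non-tumor brain, breast BrM and lung BrM, and a bar at each group's median. Pecam1 was at or above 586 CPM in each CD31 library, and Pdgfrb in the PDGFRb sort of lung BrM reached 446 CPM in 1 library and at most 43.8 CPM in the other 3.

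The first comparison asked how the sorts differ in the absence of a tumor, as a reference for the cell types they hold. Mural genes were higher in the PDGFRb sort and endothelial genes in the CD31 sort. Kcnj8, a potassium channel subunit of pericytes, was at 1458 ± 497 CPM in the PDGFRb sort and 0.408 ± 0.355 in the CD31 sort (n = 5 each), a log2 difference of 11.8 ± 1.4 (SE; 12.41 without non-tumor mouse 54132). Rgs5, a pericyte regulator of G protein signalling, was 140-fold and Acta2, smooth muscle actin, 460-fold higher in the PDGFRb sort (log2 8.85, and 9.52 without the CD31 library of mouse 56740). Cldn5, the main claudin of the blood-brain barrier, fell from 2632 ± 332 CPM in the CD31 sort to 10.7 ± 5.67 in the PDGFRb sort, and the transporters Slco1a4 and Abcb1a were 226-fold and 283-fold lower there. Of 18548 genes tested, 3227 were higher and 1946 lower in the PDGFRb sort (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05).

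All 20 measured pericyte genes rose in the PDGFRb sort, 20 also when adjusted over the list alone (camera adjusted p = 1.3e-18, adjusted p = 0.02 with an estimated correlation). Besides Kcnj8 these included Atp13a5 (log2 difference 11.31 ± 1.3) and Vtn, which encodes vitronectin (10.94 ± 1.3). Smooth muscle contractile genes rose in 16 of 19 cases and fell in 1, the same counts adjusted over the list alone (camera adjusted p = 2.3e-11, adjusted p = 0.028 with an estimated correlation). All 19 genes of the endothelial core list fell, 19 also when adjusted over the list alone (camera adjusted p = 5.2e-41, adjusted p = 0.00021 with an estimated correlation). Blood-brain barrier transport genes fell in 22 of 24 cases, with 1 up and 22 down adjusted over the list alone (camera adjusted p = 9.8e-36, adjusted p = 0.00021 with an estimated correlation). Interferon response genes fell in 34 of 39 cases and rose in 1, with 36 down and 1 up adjusted over the list alone (camera adjusted p = 3.7e-26, adjusted p = 0.019 with an estimated correlation). Gbp4, an interferon-induced GTPase with close paralogs, was at 202 ± 12.8 CPM in the CD31 sort and 0.526 ± 0.888 in the PDGFRb sort (log2 difference -8.51, and -10.48 without mouse 56740).

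The genes with the largest rises by the naming rule had no counts in the CD31 libraries of non-tumor brain. Against a floor of 3 counts over those 5 libraries, Lum and Efemp1, matrix genes of fibroblasts, were at least 3958-fold and 3807-fold higher, and Dlx6os1, Abca9 and Slc22a6 at least 2951-fold, 2021-fold and 1899-fold higher. Dlx6os1, a long RNA of GABAergic neurons, varied widely among the PDGFRb libraries (79.4 ± 90.8 CPM) and was at least 1516-fold higher without mouse 54135, and neuronal genes of the marker list rose in 8 of 12 cases, 8 adjusted over the list alone (camera adjusted p = 0.008, adjusted p = 0.22 with an estimated correlation). The largest falls were at least 986-fold for Magix, 471-fold for Tal1, a blood and endothelial transcription factor, 286-fold for Ces2e and 173-fold for Btnl9, and Scgb3a1 had a ratio of 1672 (95% counting interval 300 to 66090, at least 424 without mouse 56740). Cd276, which encodes the immune checkpoint molecule B7-H3, had 765 counts in the PDGFRb sort and 1 count in the CD31 sort of non-tumor brain, a ratio of 778 (139 to 30756, at least 213 without mouse 54132). Mouse 54135's titles and cell type labels name opposite sorts. When its libraries were placed by the cell type label, edgeR called 0 genes, with 1732 at an unadjusted p under 0.05 and 6 called by limma-voom, and the log2 difference of Dlx6os1 became -0.45.

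The main question was how the brain endothelium differs between BrM and non-tumor brain, taken as the mean of the breast and lung effects. The CD31 sort of BrM carried more RNA of vessel sprouting, basement membrane and cell division genes and less RNA of barrier transporters and capillary genes. Camera called 18 lists at its preset correlation and 0 with an estimated correlation, where the lowest adjusted p was 0.065. Plvap, which forms the diaphragms of leaky vessels, rose from 12.7 ± 3.19 CPM in non-tumor brain to 178 ± 71 in breast BrM and 254 ± 205 in lung BrM (n = 5 each). Its log2 change was 4.06 ± 0.5 (SE, adjusted p = 9.2e-06). Angpt2, a destabilising ligand of the TIE2 receptor, rose from 36.7 ± 5.29 CPM to 411 ± 184 and 295 ± 146 (log2 change 3.25 ± 0.32, adjusted p = 9.1e-07). Mfsd2a, a lipid transporter of the barrier, fell by 1.16 ± 0.26 on the log2 scale (adjusted p = 0.0024), and Cldn5 did not pass the test (log2 change -0.24 ± 0.26, adjusted p = 0.5, and 0.04 with mouse 54135 placed by its cell type label). Of 14876 genes tested, 3208 rose and 2488 fell, and 3590 of them together had an absolute log2 change of at least 1.

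The other genes chosen in advance moved in both directions. Cd276 had 1 count over the 5 non-tumor libraries and 4927 over the 10 BrM libraries, a ratio of 2834 (508 to 111974, at least 777 without non-tumor mouse 54132), and its level was 16.8 ± 7.36 CPM in breast BrM and 43.7 ± 27.6 in lung BrM. H2-Ab1, an MHC class II chain, rose 23.4-fold (log2 change 4.55 ± 0.78, adjusted p = 0.00025). Vcam1, a leukocyte adhesion receptor, fell by 1.07 ± 0.34 on the log2 scale (adjusted p = 0.019), and Icam1 did not pass the test (log2 change 0.19 ± 0.2, adjusted p = 0.51). An estimate of RNA carried over from cancer cells, scaled from the PDGFRb library of the same mouse (the carry-over share), came to 3.09% of the BrM level of Plvap, 7.3% of Angpt2, 76.2% of H2-Ab1 and 95.4% of Cd276.

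Genes of transport across the barrier fell in 16 of 24 cases and rose in 1, with 17 down and 1 up adjusted over the list alone (camera adjusted p = 8.2e-15, adjusted p = 0.15 with an estimated correlation). Slc19a3, a thiamine transporter, fell by 4.06 ± 0.26 on the log2 scale, Slc6a6, a taurine transporter, by 3.7 ± 0.22, the organic anion transporter Slc22a8 by 3.43 ± 0.29 and Slco1a4 by 3.31 ± 0.21. Capillary genes fell in 8 of 11 cases, 8 adjusted over the list alone (camera adjusted p = 9.3e-09, adjusted p = 0.065 with an estimated correlation). Among them the chemokine Cxcl12 fell by 5.22 ± 0.33 on the log2 scale, the carbonic anhydrase Car4 by 3.5 ± 0.35 and the transferrin receptor Tfrc by 2.6 ± 0.2. Tight junction genes fell in 8 of 16 cases and rose in 3, the same counts adjusted over the list alone (camera adjusted p = 0.0044, adjusted p = 0.26 with an estimated correlation). Ocln, which encodes occludin, fell by 2.94 ± 0.29 and Jam2 by 2.11 ± 0.19 on the log2 scale, while Cgn, which encodes cingulin of epithelial and endothelial junctions, rose 51.4-fold with a carry-over share of 83.7% (log2 change 5.68, and 8.83 without non-tumor mouse 54132). Genes of Wnt signalling in the barrier fell in 12 of 21 cases and rose in 1, with 14 down and 1 up adjusted over the list alone (camera adjusted p = 4e-05, adjusted p = 0.24 with an estimated correlation). Notum, a Wnt-inactivating enzyme that is itself a Wnt target, fell by 4.77 ± 0.63 on the log2 scale, Tnfrsf19 by 3.71 ± 0.4 and Reck, a co-receptor for Wnt7, by 3.23 ± 0.29.

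Tip cell and angiogenic genes rose in 17 of 26 cases and fell in 3, the same counts adjusted over the list alone (camera adjusted p = 9.3e-09, adjusted p = 0.24 with an estimated correlation). Cxcr4, a tip cell chemokine receptor, rose 128-fold, Igfbp3 59.9-fold, the peptide ligand Apln 40.3-fold and Mcam 27.4-fold, with carry-over shares of 4.11%, 0.3%, 0.0573% and 29.7%. The receptor Tek was among the members that fell, by 1.74 ± 0.16 on the log2 scale. Basement membrane genes rose in 12 of 17 cases and fell in 3, the same counts adjusted over the list alone (camera adjusted p = 7.2e-09, adjusted p = 0.091 with an estimated correlation). The laminin chain Lamb1 rose from 3.5 ± 0.949 CPM in non-tumor brain to 493 ± 202 in breast BrM and 374 ± 65.7 in lung BrM, and Col15a1 rose 172-fold, with shares of 35.1% and 35.2%. Lamc3, another laminin chain, fell by 3.98 ± 0.72 on the log2 scale. Interstitial matrix genes rose in 12 of 28 cases and fell in 1, the same counts adjusted over the list alone (camera adjusted p = 0.0028, adjusted p = 0.32 with an estimated correlation). The matrix protease Mmp14 rose 169-fold with a share of 41.1% and the protease inhibitor Timp1 45-fold with a share of 112%. Of the 12 rises of this list 9 had a share of at least 50%.

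Proliferation genes rose in 34 of 36 cases, 34 adjusted over the list alone (camera adjusted p = 1.9e-34, adjusted p = 0.065 with an estimated correlation). Their mean level was 1.71 ± 0.0843 log2(CPM + 1) in non-tumor brain, 5.26 ± 0.461 in breast BrM and 4.62 ± 0.518 in lung BrM (n = 5 each). Ccnb2, cyclin B2, rose 447-fold, and Birc5, which encodes survivin, 347-fold. The carry-over share reached 50% in 8 of the 34 members that rose. Venous genes rose in 7 of 13 cases and fell in 2, the same counts adjusted over the list alone (camera adjusted p = 0.0084, adjusted p = 0.35 with an estimated correlation). Selp, which encodes P-selectin, rose 50.5-fold and Lrg1 23-fold, with shares of 0.0728% and 1.54%. Arterial genes fell in 9 of 15 cases and rose in 3, the same counts adjusted over the list alone (camera adjusted p = 0.018, adjusted p = 0.24 with an estimated correlation), among them Gkn3 by 4.93 ± 0.54 on the log2 scale. The endothelial core list fell in 8 of 19 cases and rose in 1, the same counts adjusted over the list alone (camera adjusted p = 2.8e-05, adjusted p = 0.34 with an estimated correlation), among them Ly6c1 by 2.26 ± 0.15 on the log2 scale.

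MHC class II genes rose in 8 of 10 cases, 8 adjusted over the list alone (camera adjusted p = 0.032, adjusted p = 0.62 with an estimated correlation). Cd74, the invariant chain, was at 2.78 ± 1.29 CPM in non-tumor brain, 460 ± 478 in breast BrM and 43.2 ± 36.5 in lung BrM. All 8 rises had a carry-over share of at least 50%. Interferon response genes fell in 21 of 39 cases and rose in 4, with 23 down and 4 up adjusted over the list alone (camera adjusted p = 4.6e-05, adjusted p = 0.53 with an estimated correlation). Ifit1, an interferon-induced RNA-binding protein, fell by 2.75 ± 0.32 on the log2 scale and Gbp5 by 2.16 ± 0.56, while the transcription factor Irf8 rose 34.4-fold and Mx1 7.31-fold. Hypoxia and glycolysis genes rose in 15 of 26 cases and fell in 4, the same counts adjusted over the list alone (camera adjusted p = 0.0028, adjusted p = 0.34 with an estimated correlation), with a rise of 89.9-fold (log2 6.49, and 7.5 without non-tumor mouse 56740) and a share of 88.4% for Egln3, an oxygen-sensing enzyme. Epithelial genes rose in 15 of 19 cases, 17 adjusted over the list alone (camera adjusted p = 8.4e-05, adjusted p = 0.41 with an estimated correlation). Krt8 rose 616-fold.

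**Figure D2:**
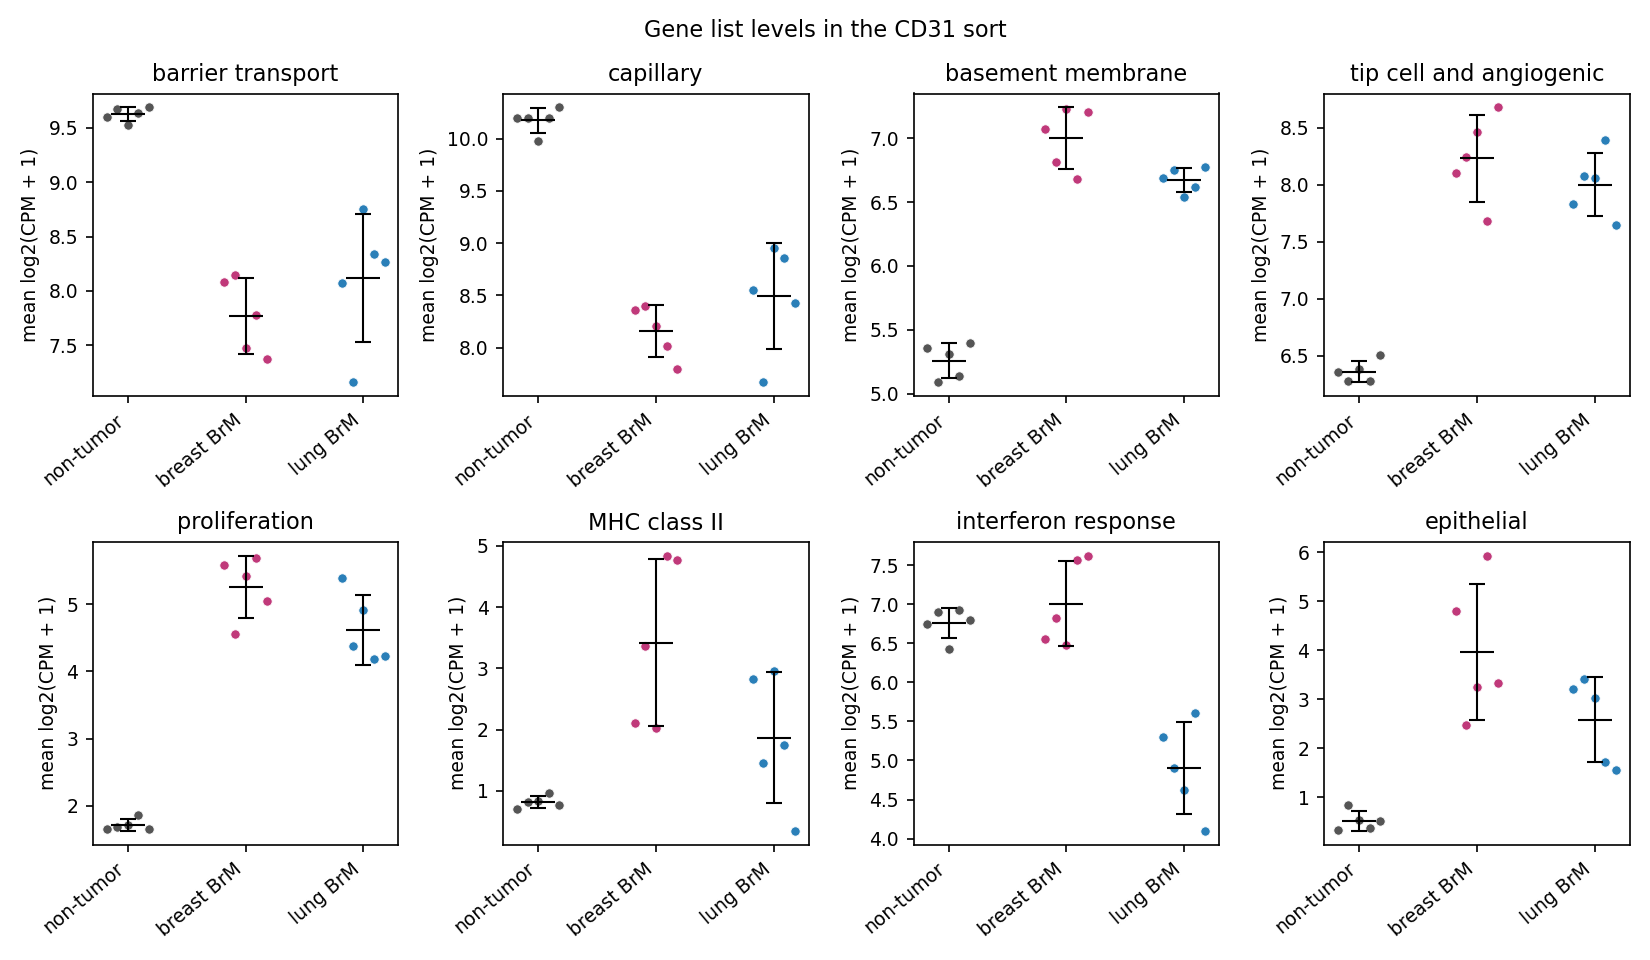
Mean log2(CPM + 1) over the genes of 8 lists in each CD31 library of non-tumor brain, breast BrM and lung BrM, with bars for the mean ± SD (n = 5 per group). Barrier transport was at 9.63 ± 0.0642 in non-tumor brain, 7.77 ± 0.35 in breast BrM and 8.12 ± 0.59 in lung BrM, and the interferon response list at 6.76 ± 0.196, 7.01 ± 0.547 and 4.91 ± 0.585.

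By the naming rule the largest rises were those of Cd276, Ms4a6d (1164-fold, a membrane protein with close paralogs), Oaf (ratio 1629, 292 to 64349), the secreted phosphoprotein Spp1 (758-fold) and Tgfbi (737-fold). Without non-tumor mouse 54132 the ratio of Oaf was at least 446 and the log2 change of Spp1 10.25 against 9.57, and without 54135 that of Tgfbi 10.34 against 9.53. The carry-over share was 1.45% for Ms4a6d, 49.9% for Oaf, 144% for Spp1 and 110% for Tgfbi. The largest falls were those of Edn3, endothelin 3, at 58.4-fold, Slc26a10 at 50.2-fold, Sgpp2, a sphingosine phosphate phosphatase, at 39.9-fold, Cxcl12 at 37.2-fold and Col14a1 at 36.5-fold (Slc26a10 -6.24 against -5.65 on the log2 scale without lung mouse 51435). The column names of the deposited tables carry 6 dates, and no date holds both breast and lung BrM. On the date with 2 breast and 1 non-tumor CD31 libraries the proliferation list was at 5.63 against 1.65 log2(CPM + 1), on that with 3 breast and 1 non-tumor libraries at 5.01 against 1.71, and on that with 2 lung and 2 non-tumor libraries at 4.56 against 1.76. With the date as a covariate, a fit added after the column names were seen, 3772 genes were called, all 5696 genes kept their direction, and the log2 change was 3.5 for Plvap, 3.31 for Angpt2, -0.93 for Mfsd2a and -1.3 for Vcam1.

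Comparing each origin with the same non-tumor libraries asked whether breast and lung metastases change the endothelium alike. In breast BrM 2772 genes rose and 1701 fell, and in lung BrM 3032 rose and 2150 fell. Mfsd2a fell by 1.68 ± 0.32 on the log2 scale in breast BrM (adjusted p = 0.00084), while in lung BrM its change of -0.65 ± 0.32 did not pass (adjusted p = 0.12). Vcam1 fell by 1.53 ± 0.41 in breast BrM (adjusted p = 0.0092) and did not pass in lung BrM (-0.62 ± 0.4, adjusted p = 0.24), and the difference between the origins did not pass for either gene (adjusted p = 0.12 for Mfsd2a and 0.3 for Vcam1). Ratios for Cd276 were 1721 (309 to 68036) in breast BrM and 4111 (737 to 162443) in lung BrM (at least 472 and 1127 without non-tumor mouse 54132), with carry-over shares of 282% and 18.8%. H2-Ab1 rose 63.1-fold in breast BrM and 8.68-fold in lung BrM, with shares of 70.4% and 103% (log2 5.98 in breast BrM, and 5.36 without mouse 53142). With the date as a covariate 2291 genes were called in breast BrM and 1458 in lung BrM, and neither Vcam1 in breast BrM (log2 change -1.22, adjusted p = 0.13) nor H2-Ab1 in lung BrM (3.2, adjusted p = 0.2) passed.

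In breast BrM the largest rises were those of Slpi, a protease inhibitor of epithelia (ratio 1493, 413 to 12336), Lrrc66 (1322, 452 to 6414), Ms4a6d (958-fold) and Ubd, an interferon-inducible ubiquitin-like protein (948-fold), besides Cd276. The carry-over share was 96% for Slpi and 69.4% for Lrrc66, and without the library of mouse 51950 the ratio of Slpi was 868. Without non-tumor mouse 54132 Lrrc66 was at least 1087-fold higher, without breast mouse 53072 its ratio was 882, and without non-tumor mouse 56727 the log2 change of Ubd was 11.47 against 9.89. Ttr, which encodes transthyretin of the choroid plexus, fell 126-fold from a variable 65.3 ± 66.2 CPM, Slc26a10 69-fold, Edn3 60-fold, Col14a1 51.7-fold and Sgpp2 44-fold. Without mouse 51950 the log2 changes of Ttr and Slc26a10 went from -6.97 and -6.11 to -11.54 and -7.08, and without 52599 that of Col14a1 from -5.69 to -6.78. MHC class I genes rose in 8 of 22 cases, 8 adjusted over the list alone (camera adjusted p = 0.029, adjusted p = 0.66 with an estimated correlation). H2-Q7 rose 12.2-fold and H2-K1 2.18-fold, with shares of 38.2% and 39.3% of the level and 42.1% and 75.9% of the rise, although reads of this family cannot be placed on 1 member with certainty. Interferon response genes rose in 7 of 39 cases and fell in 5, the same counts adjusted over the list alone, and the list did not pass (camera adjusted p = 0.9). Mx1 rose 21.2-fold and Zbp1, a nucleic acid sensor, 7.34-fold, with shares of 34.1% and 58.7% of the level and 36% and 69.2% of the rise. Tight junction genes fell in 7 of 16 cases and rose in 3, the same counts adjusted over the list alone (camera adjusted p = 0.0023, adjusted p = 0.19 with an estimated correlation). Their median log2 change of -0.49 had the opposite sign to their mean of 0.13. Proliferation genes rose in 34 of 36 cases, 34 adjusted over the list alone (camera adjusted p = 6.2e-41, adjusted p = 0.038 with an estimated correlation).

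Of the largest rises in lung BrM, Krt20 and Msln had no counts in non-tumor brain and were at least 1350-fold and 1294-fold higher against a floor of 3 counts over its 5 libraries. Krt19 had a ratio of 7034 (1947 to 58088), Gc, the vitamin D binding protein, 8219 (1475 to 324691) and the retinol binding protein Rbp4 7652 (1373 to 302294), and their carry-over shares were 87.8%, 157% and 110%. Without the library of mouse 51435 Krt20 was at least 799-fold higher, and the ratios were 4245 for Krt19, 2862 for Gc and 2930 for Rbp4, which without non-tumor mouse 54135 were at least 2197-fold and 2046-fold higher. The largest falls reported were Edn3 (56.9-fold), Gkn3 (39.5-fold), Slc26a10 (36.6-fold), Alpl (36.5-fold) and Sgpp2 (36.3-fold). Log2 changes went from -5.19 to -6.37 for Slc26a10 without mouse 51435, -5.83 to -6.48 for Edn3 and -5.19 to -6.81 for Alpl without 55169-70, and -5.31 to -6.1 for Gkn3 without 56195-56520. Interferon response genes fell in 34 of 39 cases and rose in 1, the same counts adjusted over the list alone (camera adjusted p = 5.7e-14, adjusted p = 0.3 with an estimated correlation). Ifit1 went from 220 ± 50.5 CPM in non-tumor brain to 12.1 ± 6.22 in lung BrM (n = 5 each), Oas2 fell 13.4-fold and Gbp5 11.4-fold.

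Breast and lung BrM shared 2222 genes that rose and 1217 that fell, where independent lists of these sizes would share 565 and 246, and 13 genes were called in opposite directions. As controls are shared, groups simulated without effects gave a correlation of log2 changes across genes of 0.501, against 0.798 observed. They called at most 1 gene up or down, too few to test sharing. The covariance was 2.71 against 0.159 simulated, a difference of 2.55. With the 5 controls split between comparisons, new fits shared on average 1115 rises (161 for independent lists) and 673 falls (76.9), with a correlation of 0.618. Genes are not independent, so these correlations have no p-value.

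**Figure D3:**
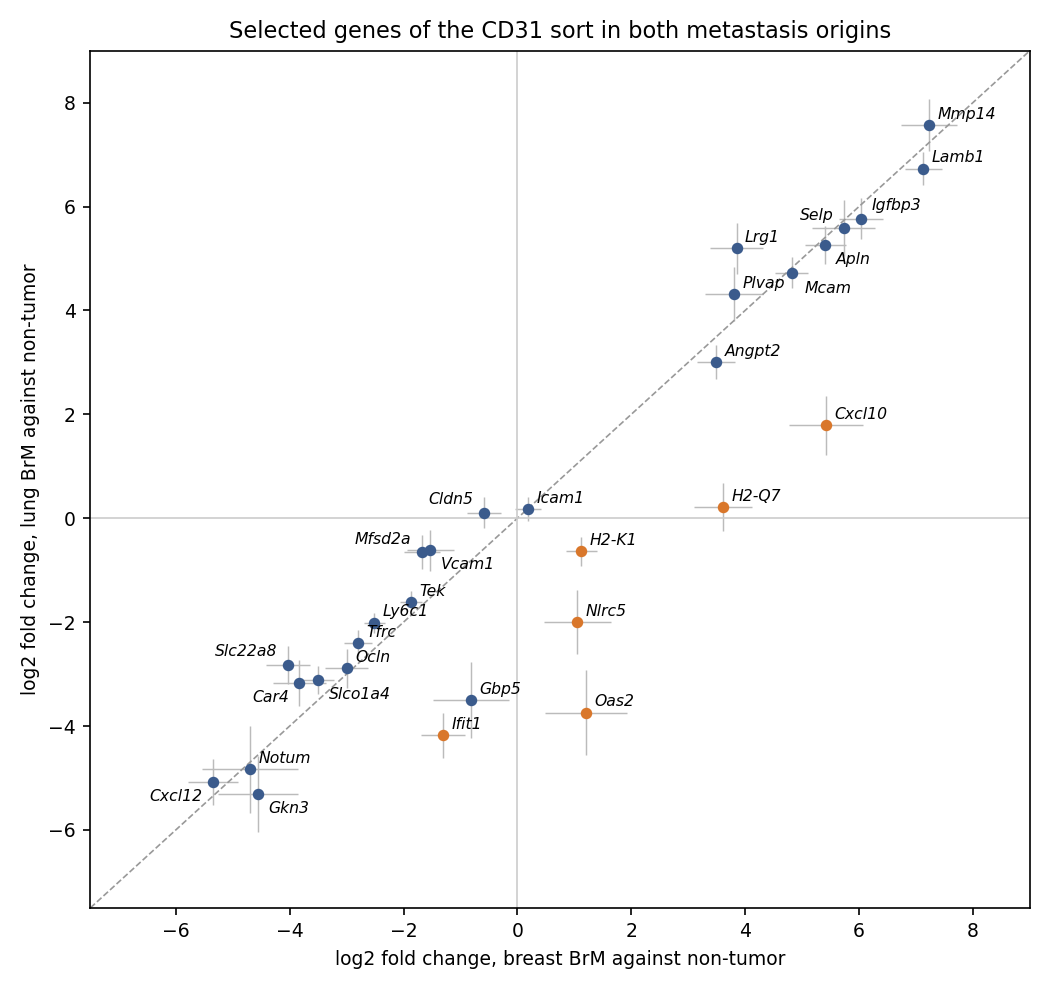
Log2 fold change against non-tumor brain in breast BrM (horizontal axis) and lung BrM (vertical axis) of 30 selected genes in the CD31 sort, with bars of ± 1 SE and a dashed line of equal change. Orange marks the 6 genes that differed between lung and breast BrM, and Igfbp3 had log2 changes of 6.04 in breast and 5.77 in lung BrM.

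The direct comparison of lung with breast BrM asked which genes of the CD31 sort differ with the tumor of origin. Interferon response genes were lower in the CD31 sort of lung BrM by camera (adjusted p = 0.031 with an estimated correlation), while the lower MHC class I list did not pass in that form (adjusted p = 0.19). Oas2, an interferon-induced antiviral enzyme, was at 2.04 ± 2.18 CPM in lung and 63.7 ± 34.7 in breast BrM (n = 5 each), a log2 difference of -4.94 ± 0.85 (SE, adjusted p = 0.0047). The chemokines Cxcl9, Cxcl11 and Cxcl10, ligands of the chemokine receptor CXCR3, were 77.7-fold, 12.8-fold and 12.4-fold lower in lung BrM (log2 differences of Cxcl9 and Cxcl11 -6.28 and -3.68, and -7.52 and -4.42 without lung mouse 51435). Their levels in breast BrM had carry-over shares of 32.7%, 5.3% and 81.1%, and that of Oas2 31.1%. Of 14876 genes tested, 86 were higher and 231 lower in lung BrM. Cd276 did not differ by the test (log2 difference 1.38 ± 0.64, adjusted p = 0.33). Neither did H2-Ab1 (-2.86 ± 0.74, adjusted p = 0.056, and -2.24 without breast mouse 53142).

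Interferon response genes were lower in lung BrM in 29 of 39 cases, 38 adjusted over the list alone (camera adjusted p = 3.7e-62, adjusted p = 0.031 with an estimated correlation). Besides Oas2, Ifit2 was 11-fold, Gbp6 10.7-fold and Mx2 8.75-fold lower, with shares of 17.3%, 74.3% and 72.4%. MHC class I genes were lower in 10 of 22 cases, 15 adjusted over the list alone (camera adjusted p = 1.2e-17, adjusted p = 0.19 with an estimated correlation). H2-Q7 was 10.5-fold, H2-Q6 10.4-fold, H2-K1 3.41-fold and Nlrc5, a transactivator of MHC class I genes, 8.31-fold lower. The H2 genes share sequence with other family members. Cd274, which encodes the checkpoint ligand PD-L1, was 5.21-fold lower. The endothelial transcription factor Sox17 was 2.13-fold higher in lung BrM, with a share of 0.0494%. Clu, which encodes clusterin, was 7.55-fold higher and the iron-binding lipocalin Lcn2 12.8-fold lower, with shares of 123% and 102% in the higher group (Lcn2 -3.68 on the log2 scale, and -2.8 without breast mouse 53072).

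By the naming rule the largest differences were as follows. Hnf4a, a transcription factor of gut and liver epithelia, had no counts in breast BrM and was at least 704-fold higher in lung BrM, Rbp4 had a ratio of 7108 (1275 to 280790), Apob 2811 (778 to 23222), Gc 2545 (870 to 12343) and Msln 1803 (499 to 14893). Tfap2c and Atp6v1b1 had no counts in lung BrM and were at least 877-fold and 605-fold higher in breast BrM, Sox10 had a ratio of 3199 (574 to 126389) and BC006965 of 2143 (384 to 84672). Without the lung library of mouse 51435 the ratios were 2721 for Rbp4, 1274 for Apob and 886 for Gc, and Rbp4 and Msln were at least 1900-fold and 1018-fold higher without breast mice 52865 and 52599. Without the breast library of mouse 53072 Tfap2c and Atp6v1b1 were at least 526-fold and 223-fold higher in breast BrM, with ratios of 2049 for Sox10 and 1270 for BC006965, which were at least 867-fold and 581-fold higher without lung mouse 54957. Csn3, the milk protein kappa casein, was at 2657 ± 3620 CPM in breast and 1.7 ± 0.772 in lung BrM. Epithelial genes of the marker list were higher in lung BrM in 1 of 19 cases and lower in 4, with 2 up and 8 down adjusted over the list alone (camera adjusted p = 0.024, adjusted p = 0.66 with an estimated correlation), with Krt19 443-fold higher and Cldn4 612-fold lower. Their log2 differences of 8.79 and -9.26 were 10.38 and -8 without breast mouse 53072 (Csn3 -9.27 against -10.6) and 8.2 and -10.82 without lung mouse 51435. The count of 317 genes became 138 without genes whose carry-over share reached 50% of the higher level, 199 without the breast library of mouse 53072 and 484 without lung mouse 56195-56520. With the date as a covariate edgeR called 0 genes, with 955 at an unadjusted p under 0.05 and 1 called by limma-voom. The median log2 difference of the 231 lower genes was -3.75 with and -3.39 without the date. Non-tumor libraries put the interferon list at 6.86 log2(CPM + 1) on the date of 2 lung libraries (4.36), and at 6.75 and 6.43 on dates of breast libraries (7.06 and 6.97).

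The PDGFRb sort was compared in the same way to ask how mural cells differ between BrM and non-tumor brain. In the mean of both origins camera called 24 lists, with epithelial and MHC class I genes higher and smooth muscle genes lower in BrM, and 0 with an estimated correlation, where the lowest adjusted p was 0.24. Acta2 was at 8566 ± 4824 CPM in non-tumor brain (n = 5), 3339 ± 2103 in breast BrM (n = 4) and 563 ± 932 in lung BrM (n = 4), a fall by 2.64 ± 0.75 on the log2 scale (adjusted p = 0.026). Rgs5 did not pass (log2 change -1.25 ± 0.63, adjusted p = 0.2), but did without lung mouse 51435 (-2.4, with -3.99 for Acta2), nor did the collagen Col1a1 (1.64 ± 0.7, adjusted p = 0.13, 0.63 without this mouse) or Icam1 (2.22 ± 0.83, adjusted p = 0.082). Cd276 rose 9.34-fold (adjusted p = 0.0016) and H2-Ab1 17.1-fold (adjusted p = 0.012). Vcam1 rose 2.76-fold in the mean of both origins (adjusted p = 0.00095), which joined a fall in breast BrM and a rise in lung BrM. Of 17028 genes tested, 1524 rose and 1462 fell. The count of 2986 was 6317 without the small library of mouse 51950, and 1875 without non-tumor mouse 56740 and 1943 without non-tumor mouse 56727. Without the 3 lung libraries with Pdgfrb under 50 CPM, a fit added after these levels were seen, it was 458.

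Epithelial genes rose in 14 of 19 cases, 15 adjusted over the list alone (camera adjusted p = 8.4e-17, adjusted p = 0.24 with an estimated correlation), with Krt8 424-fold higher. Pericyte genes fell in 9 of 20 cases, 12 adjusted over the list alone (camera adjusted p = 5.4e-08, adjusted p = 0.45 with an estimated correlation), among them Ecm2 by 4.03 ± 0.82 on the log2 scale. Smooth muscle contractile genes fell in 13 of 19 cases and rose in 1, with 16 down and 2 up adjusted over the list alone (camera adjusted p = 9e-07, adjusted p = 0.45 with an estimated correlation). Pln, which encodes phospholamban, fell 115-fold and Myh11, smooth muscle myosin, 15.5-fold, while Tes, a focal adhesion protein, rose 40.6-fold. Interstitial matrix genes rose in 11 of 36 cases and fell in 1, with 14 up and 3 down adjusted over the list alone (camera adjusted p = 0.00023, adjusted p = 0.5 with an estimated correlation). Fn1, fibronectin, rose from 54.2 ± 22 CPM (n = 5) to 1373 ± 513 in breast BrM and 2822 ± 813 in lung BrM (n = 4 each), the tenascin Tnc rose 49.4-fold and Timp1 35.4-fold. Basement membrane collagen Col18a1 rose 3.93-fold. Without lung mouse 51435 log2 changes went from -4.03 to -5.75 for Ecm2, -6.84 to -7.8 for Pln, -3.96 to -5.02 for Myh11 and 5.63 to 4.18 for Tnc.

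The MHC class I list rose in 17 of 22 cases, 20 adjusted over the list alone (camera adjusted p = 2.9e-13, adjusted p = 0.37 with an estimated correlation), with the immunoproteasome subunit Psmb8 8.66-fold higher. MHC class II genes rose in 5 of 12 cases, 6 adjusted over the list alone (camera adjusted p = 0.00073, adjusted p = 0.46 with an estimated correlation), with Cd74 20.5-fold higher. Interferon response genes rose in 15 of 39 cases, 15 adjusted over the list alone (camera adjusted p = 1.5e-08, adjusted p = 0.45 with an estimated correlation), with Oas1a, a member of a family of near copies, 33.3-fold higher. Proliferation genes rose in 4 of 36 cases, 4 adjusted over the list alone (camera adjusted p = 5.5e-06, adjusted p = 0.45 with an estimated correlation), from a level that varied among non-tumor libraries (3.99 ± 1.17 log2(CPM + 1), n = 5).

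Among markers of neural cells, those of neurons and astrocytes were lower in the PDGFRb sort of BrM and those of oligodendrocytes were not. Neuronal genes fell in 8 of 10 cases, 8 adjusted over the list alone (camera adjusted p = 0.00098, adjusted p = 0.45 with an estimated correlation), and astrocyte genes fell in 7 of 13 and rose in 1, with 9 down and 3 up adjusted over the list alone (camera adjusted p = 0.0075, adjusted p = 0.5 with an estimated correlation). The glutamate transporter Slc1a2 fell 28.8-fold and Ntsr2, an astrocyte neurotensin receptor, 76.6-fold. Oligodendrocyte genes rose in 2 of 13 cases, 2 adjusted over the list alone (camera adjusted p = 0.0096, adjusted p = 0.45 with an estimated correlation). The largest falls by the naming rule were Miat (1183-fold, with 4 counts left in BrM), Gad2, the GABA-synthesising enzyme (782-fold), Acsl6 (359-fold), Kcna5 (253-fold) and Slc39a12 (188-fold). Log2 changes went from -10.21 to -9.21 for Miat and -9.61 to -8.3 for Gad2 without non-tumor mouse 54135, and to -11.77 for Gad2 without lung mouse 54957, from -8.49 to -9.31 and -9.14 for Acsl6 without breast 52865 and lung 56195-56520, -7.99 to -8.83 for Kcna5 without lung 51435 and -7.55 to -8.19 for Slc39a12 without breast 53072. The largest rises were Krt8, Foxa1, a transcription factor of epithelia (ratio 1304, 234 to 51534), Irx5 (287, 98 to 1394, and 162 without breast mouse 51950), Dlk1 (267-fold) and Rnf128 (248-fold). Foxa1 was at least 352-fold higher without non-tumor mouse 54135, and log2 changes went from 7.95 to 6.63 for Rnf128 and 8.06 to 7.36 for Dlk1 without breast 51950, with 7.1 and 8.75 for Dlk1 without lung 51435 and non-tumor 54135.

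**Figure D4:**
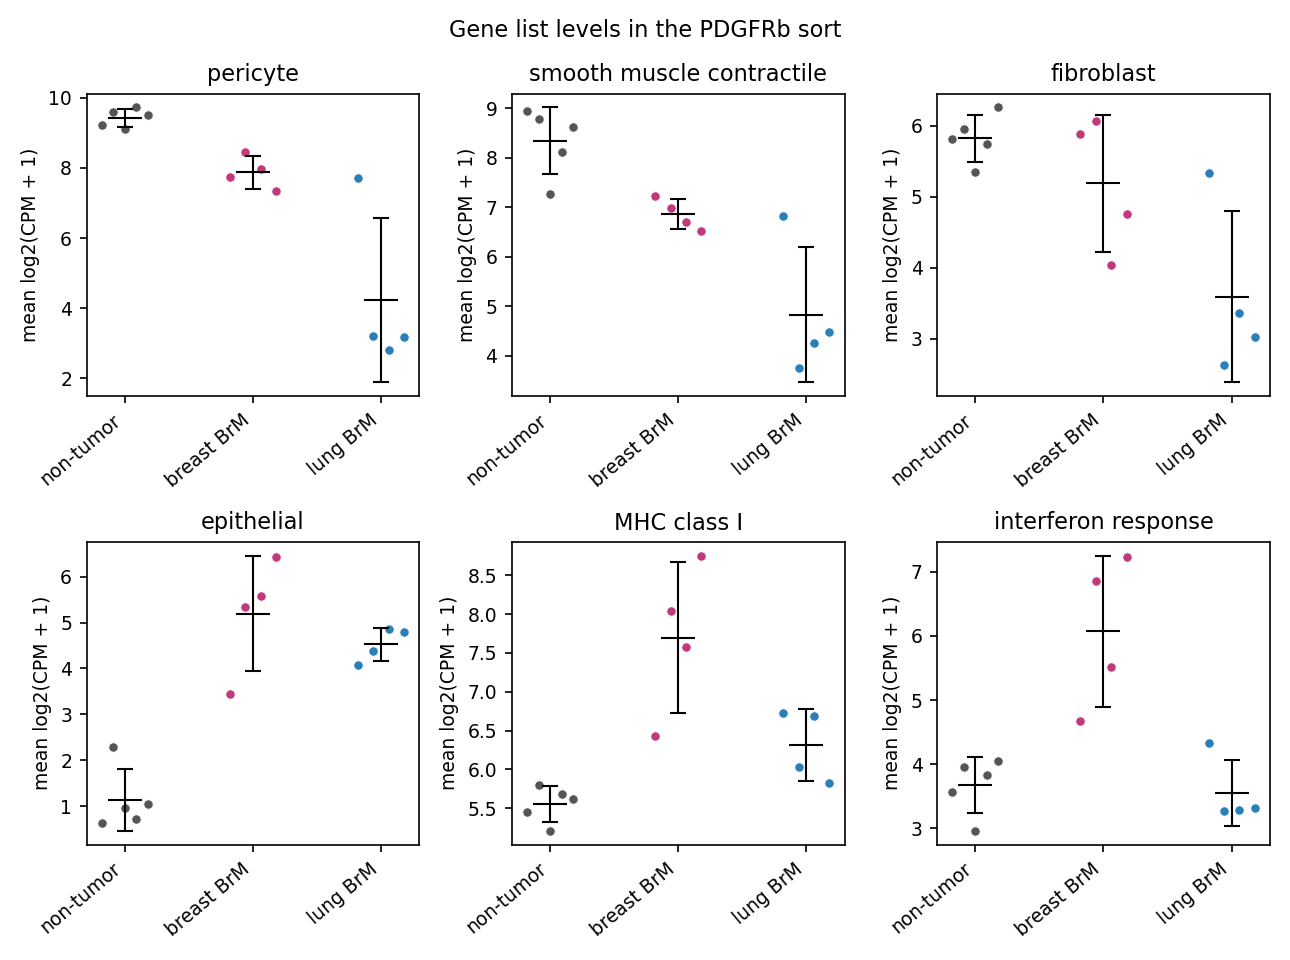
Mean log2(CPM + 1) over the genes of 6 lists in each PDGFRb library of non-tumor brain (n = 5), breast BrM (n = 4) and lung BrM (n = 4), with bars for the mean ± SD. The pericyte list was at 9.43 ± 0.261 in non-tumor brain, 7.87 ± 0.472 in breast BrM and 4.23 ± 2.33 in lung BrM, and the epithelial list at 1.13 ± 0.67, 5.2 ± 1.26 and 4.53 ± 0.361.

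In breast BrM 1073 genes of the PDGFRb sort rose and 458 fell, with a share of cancer RNA not tested. Interferon response genes rose in 24 of 39 cases, 34 adjusted over the list alone (camera adjusted p = 9.7e-28, adjusted p = 0.084 with an estimated correlation). Oas1a rose 89.9-fold and Gbp4 76.5-fold. MHC class I genes rose in 17 of 22 cases, 21 adjusted over the list alone (camera adjusted p = 1.3e-23, adjusted p = 0.084 with an estimated correlation), with H2-Q7 77.5-fold higher. Chemokine and cytokine genes rose in 11 of 32 cases and fell in 1, with 15 up and 2 down adjusted over the list alone (camera adjusted p = 3.7e-05, adjusted p = 0.28 with an estimated correlation), with Cxcl9 543-fold higher. Without breast mouse 53072 log2 changes went from 6.26 to 5.51 for Gbp4 (8.2 without non-tumor 56740), 9.08 to 8.1 for Cxcl9 (10.74 without 56727) and 6.28 to 5.41 for H2-Q7. Interstitial matrix genes rose in 15 of 36 cases, with 24 up and 1 down adjusted over the list alone (camera adjusted p = 9.2e-13, adjusted p = 0.28 with an estimated correlation). Col1a1 rose 8.16-fold (adjusted p = 0.033, not passed without mouse 51950), Tnc 98.4-fold, Mmp9 77.6-fold and Col6a3 58.9-fold, and the basement membrane genes Col18a1 and Col4a1 rose 6.32-fold and 4.98-fold. Vcam1 fell by 1.04 ± 0.26 on the log2 scale (adjusted p = 0.025), Cd276 rose 9.82-fold (adjusted p = 0.0038; log2 3.3, and 2.68 without mouse 51950) and Acta2 did not pass (-1.36 ± 0.92, adjusted p = 0.4).

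No pericyte gene of 20 passed in breast BrM, 0 adjusted over the list alone (camera adjusted p = 0.14). Smooth muscle contractile genes fell in 2 of 19 cases and rose in 1, with 3 down and 2 up adjusted over the list alone (camera adjusted p = 0.041, adjusted p = 0.63 with an estimated correlation), with Pln 77.4-fold lower (log2 -6.27, and -7.18 without mouse 53072). Epithelial genes rose in 15 of 19 cases, 17 adjusted over the list alone (camera adjusted p = 4.5e-20, adjusted p = 0.084 with an estimated correlation), and Krt8 rose 197-fold. The largest rises were Wfdc5, which had no counts in non-tumor brain (at least 997-fold against 3 counts over its 5 libraries), Aldh3b2 (ratio 2480, 686 to 20489), Atp6v1b1 (1717-fold), Mmp10 (1694-fold, log2 10.73, and 9.05 without mouse 52599) and Irx5 (ratio 472, 161 to 2292). The largest falls were at least 631-fold for Miat and 584-fold for Gad2, with ratios of 5712 (1025 to 225645) for Acsl6, 5361 (962 to 211777) for Dlx1 and 1702 (305 to 67265) for Slc47a1. Without mouse 51950 the values were at least 507-fold for Wfdc5 and a ratio of 221 for Irx5, and without non-tumor mouse 54135 at least 293-fold for Miat and 220-fold for Gad2 and a ratio of 2340 for Dlx1. Acsl6 and Slc47a1 were at least 1186-fold and 353-fold lower without breast mouse 52865, and Dlx1 1402-fold without 53072. The count of 1531 genes was 3289 without the library of mouse 51950 and 830, 833, 883 and 921 without non-tumor mice 56740, 56727, 53680 and 54135, and 983 without breast mouse 53072. With the date as a covariate it was 115, and all called genes kept their direction.

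In lung BrM alone 1687 genes of the PDGFRb sort rose and 1290 fell, in libraries of which 3 had Pdgfrb under 50 CPM. Xist, an RNA of female cells, was at 18.3, 36 and 17.8 CPM in these 3 and at 493, 368 and 589 CPM in the CD31 libraries of the same mice, while mouse 51435 had 179 CPM in the PDGFRb and 331 in the CD31 library. Pericyte genes fell in 12 of 20 cases, 20 adjusted over the list alone (camera adjusted p = 2.4e-12, adjusted p = 0.53 with an estimated correlation). Rgs5 fell 6.02-fold and Ecm2 29.4-fold. Smooth muscle contractile genes fell in 15 of 19 cases and rose in 1, with 16 down and 1 up adjusted over the list alone (camera adjusted p = 1.3e-08, adjusted p = 0.53 with an estimated correlation), with Pln 171-fold and Acta2 15.2-fold lower. Without mouse 51435 the log2 changes went from -2.59 to -4.84 for Rgs5, -4.88 to -8.27 for Ecm2, -7.42 to -9.28 for Pln and -3.93 to -6.56 for Acta2. Epithelial genes rose in 12 of 19 cases, 13 adjusted over the list alone (camera adjusted p = 9.3e-11, adjusted p = 0.53 with an estimated correlation), with Krt8 913-fold higher. Fn1 rose 52.1-fold, Vcam1 15.6-fold (adjusted p = 1.3e-06), Icam1 10.2-fold (adjusted p = 0.025) and Cd276 8.88-fold (adjusted p = 0.0025). Interferon response genes rose in 2 of 39 cases and fell in 1, the same counts adjusted over the list alone (camera adjusted p = 0.86), and Cmpk2 fell 42.3-fold (log2 -5.4, and -6.69 without mouse 54957).

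The largest rises in lung BrM had no counts in non-tumor brain and were at least 4649-fold for Serpina1c, 4153-fold for Tff3, 2942-fold for Tff2, 2053-fold for Gsta1 and 2020-fold for Eps8l3. The largest falls were Dpysl5 (ratio 3412, 612 to 134792), Kcna5 (2129, 382 to 84108), Slc6a11, a GABA transporter (434-fold), Dpep1 (539, 184 to 2614) and Miat (377-fold). Without lung mouse 56195-56520 the rises were at least 592-fold for Tff3, 1426-fold for Tff2 and 1002-fold for Eps8l3, and without non-tumor mouse 54135 the ratio of Dpysl5 was 1278 and the log2 change of Miat -7.59 against -8.56. Dpysl5 and Kcna5 were at least 793-fold and 495-fold lower without lung mouse 51435, and the log2 change of Slc6a11 was -10.61 against -8.76 without 54957. The count of 2977 genes was 161 when the only lung library left was that of mouse 51435, whose Pdgfrb was above 50 CPM, and 6961 without the breast library of mouse 51950, which enters the shared spread. It was 1801, 1841 and 1856 without lung mice 55169-70, 54957 and 56195-56520.

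Breast and lung BrM shared 675 genes that rose and 265 that fell in the PDGFRb sort, against 106 and 34.7 for independent lists, and 14 were called in opposite directions. The correlation of log2 changes across genes was 0.553 against 0.431 in simulated groups without effects, and the covariance 2.94 against 0.393, a difference of 2.55. With the controls split, new fits shared 132 rises (8.11 for independent lists) and 59 falls (2.84), with a correlation of 0.411.

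Lung and breast BrM were also compared directly in the PDGFRb sort. Vcam1 was at 1401 ± 207 CPM in lung and 43.7 ± 16.3 in breast BrM (n = 4 each), a log2 difference of 5 ± 0.32 (adjusted p = 4.3e-06). Interferon response genes were lower in lung BrM in 21 of 39 cases, 35 adjusted over the list alone (camera adjusted p = 9.5e-26, adjusted p = 0.34 with an estimated correlation), with Cmpk2 345-fold lower (log2 -8.43, and -9.72 without lung mouse 54957). Among MHC class I genes 8 of 22 were lower and 1 higher, with 13 down and 2 up adjusted over the list alone (camera adjusted p = 4.5e-08, adjusted p = 0.47 with an estimated correlation), with H2-Q7 about 100-fold and H2-K1 9.93-fold lower (H2-Q7 -6.64 on the log2 scale, -5.84 without breast mouse 53072 and -7.36 without lung mouse 55169-70). Pericyte genes were lower in 1 of 20 cases, 9 adjusted over the list alone (camera adjusted p = 1.7e-14, adjusted p = 0.47 with an estimated correlation), with the aminopeptidase Anpep 6.94-fold lower. Basement membrane genes were lower in 5 of 18 cases, with 13 down and 1 up adjusted over the list alone (camera adjusted p = 8.9e-10, adjusted p = 0.47 with an estimated correlation), with Col15a1 15.3-fold lower. Without lung mouse 51435 the log2 differences went from -2.8 to -4.02 for Anpep and -3.94 to -5.69 for Col15a1. In total 524 genes were higher and 407 lower in lung BrM.

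Of the largest differences by the naming rule, Serpina1a and Serpina1c, near copies whose reads cannot be told apart with certainty, were at least 3132-fold and 3133-fold higher in lung BrM, Ugt2b34 2037-fold, Tff2 1982-fold and Ctse 1757-fold. Wfdc5, Elf5, a transcription factor of mammary epithelium, and Hs3st3a1 were at least 712-fold, 564-fold and 471-fold higher in breast BrM. Hs3st3a1 varied widely there (52.8 ± 102 CPM, n = 4), and without the library of mouse 51950 it was at least 46.5-fold and Wfdc5 362-fold higher, while Tff2 was at least 961-fold higher in lung BrM without mouse 56195-56520. Aldh3b2 had a ratio of 3542 (635 to 139953, at least 823 without lung mouse 51435), and Csn3 was at 7540 ± 4914 CPM in breast and 1.82 ± 0.811 in lung BrM. Krt19 was 1318-fold higher and Lcn2 42.9-fold lower in lung BrM, and without breast mouse 53072 Lcn2 did not pass (log2 -4.76 against -5.42) and Krt19 was at 11.77 against 10.36. The count of 931 was 2688 without the breast library of mouse 51950, 1594 without lung mouse 51435, 349, 350 and 377 without lung mice 54957, 56195-56520 and 55169-70, and 517 and 617 without breast mice 52599 and 52865. It was 26 with lung mouse 51435 as the only lung library, and 102 with the date as a covariate. As no date holds both origins, the date and the origin were not separated within any date.

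The last comparison tested whether the BrM effect differs between the sorts, as the PDGFRb effect minus the CD31 effect. Fn1 rose in the PDGFRb sort and stayed near 2189 ± 259 CPM in the CD31 sort of non-tumor brain, with 1927 ± 781 in breast and 2319 ± 749 in lung BrM, and its effect was 5.19 ± 0.4 log2 units higher in the PDGFRb sort (adjusted p = 4.1e-09). Apln and Lamb1 had effects 592-fold and 38.2-fold smaller in the PDGFRb sort, and Angpt2 differed by -4.37 ± 0.8 (adjusted p = 0.00056, and -5.51 without lung mouse 51435). Apln went from -9.21 to -9.89, -9.83 and -8.6 without PDGFRb libraries 53072, 54957 and 54135. Vcam1 rose in the PDGFRb sort, from lung BrM alone, and fell in the CD31 sort, a difference of 2.55 ± 0.45 (adjusted p = 0.00035), while in breast BrM it fell in both sorts. Cldn5 and Mfsd2a differed by -3.04 ± 0.54 and -3.31 ± 0.75, from levels in the PDGFRb sort of 10.7 ± 5.67 and 24.5 ± 24.4 CPM in non-tumor brain (Mfsd2a -2.63 without mouse 54135). Of 18548 genes, 665 had a higher and 1184 a lower effect in the PDGFRb sort, 1849 in all, and with the mouse as a block, which pairs both sorts of a mouse, 745 passed. The count was 3054 without the breast PDGFRb library of mouse 51950 and 717 without the 3 lung PDGFRb libraries with low Pdgfrb.

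Interferon response effects were higher in the PDGFRb sort for 24 of 39 genes and lower for 1, with 31 up and 1 down adjusted over the list alone (camera adjusted p = 2.6e-23, adjusted p = 0.11 with an estimated correlation), with differences of 6.18 ± 1 for Gbp4 and 5.02 ± 0.75 for Oas1a. MHC class I effects were higher for 13 of 22 genes, 17 adjusted over the list alone (camera adjusted p = 8.6e-18, adjusted p = 0.11 with an estimated correlation), with 3.57 ± 0.4 for H2-T23. Proliferation effects were lower for 22 of 36 genes, 24 adjusted over the list alone (camera adjusted p = 5.9e-22, adjusted p = 0.12 with an estimated correlation), with -6.31 ± 0.69 for Birc5, which had 18.3 ± 14.9 CPM in the PDGFRb sort of non-tumor brain and 0.192 ± 0.155 in the CD31 sort. With mouse 54135 placed by its cell type label the differences became -0.22 for Gbp4 and 0.05 for Birc5. The largest differences by the naming rule were higher for the adaptor Grb7 (9.71 ± 1.2), Pllp (8.8 ± 1.2), Eps8l2 (7.88 ± 1), Sema3c (7.45 ± 1.2) and Rab11fip1 (7.26 ± 1). They were lower for Npr3, the natriuretic peptide clearance receptor with no counts in the PDGFRb sort of lung BrM, Crmp1 (-10.69 ± 1.5), Oaf, with 1 count in the CD31 sort of non-tumor brain, Tgfbi (-9.81 ± 0.94) and Mpp3 (-9.77 ± 1.2). Without non-tumor 56740 Grb7 was at 12.11, Sema3c at 8.29 and Gbp4 at 8.14, without 54135 Tgfbi at -10.61 (CD31), Crmp1 at -9.57 and Mpp3 at -8.51, and Mpp3 at -10.38 without lung 55169-70. Among 14191 genes tested in both sorts, 850 rose and 298 fell in both, against 296 and 135 for independent lists, and 169 were called in opposite directions.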

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

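Tests chosen after the results were seen are those of swapped libraries, depth, Xist, carried-over RNA (Cd276, proliferation and interferon genes included) and diluted endothelial genes, and the fits with dates or without low-Pdgfrb libraries.

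A single library stood far from the rest of its group by Dixon's test in 11 of 71 groups tested over 12 quantities, where chance gives about 1 in 20 groups, or 3.6. The lung PDGFRb library of mouse 51435 stood apart in 4 of them, with 446 CPM of Pdgfrb, a pericyte list level of 7.72, an endothelial core level of 2.72 and an interferon level of 4.33 log2(CPM + 1). Epcam was at 411 CPM in the CD31 breast library of mouse 53072 and at 38.5 CPM in the CD31 lung library of mouse 54957. Non-tumor mouse 54132 had 0.763 CPM of Epcam in its CD31 library and 6.15 CPM in its PDGFRb library, an epithelial list level of 2.29 in the latter, and 0.0587 CPM of Cd276, which is 1 count, in the former. The proliferation list was at 1.86 in the CD31 library of non-tumor mouse 56727.

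The low mural and high epithelial RNA of the PDGFRb sort of lung BrM may come from cancer cells in the gate. Lower mural genes in the mice's own cells, without other cells, are excluded for the 3 libraries with low Pdgfrb, whose Xist was at most 9.8% of that in the CD31 library of the same mouse, against 63.9% to 193% in 7 female breast and non-tumor mice. Relative to non-tumor PDGFRb libraries (Xist of 3 female mice, 755 CPM on average), the 3 low-Pdgfrb libraries kept 2.42%, 4.77% and 2.36% of Xist and 2.82%, 2.98% and 3.39% of Pdgfrb. Mouse 51435 kept 23.8% and 34.5%, as RNA of cells without Xist would give. Whether fewer mural cells were present with lung tumors stays open, as does the Xist level of the cancer cells alone, not analysed here, and an added fall of some mural genes (median log2 changes of -3.27 for pericyte, -3.74 for smooth muscle and -1.65 for fibroblast genes, a spread of 2.09 ± 1 SE). Swapped sorts are excluded, as Pecam1 reached at most 0.472 CPM in these libraries against at least 586 in the lung CD31 libraries, and so is lower depth, as 2 of the 3 libraries with low Pdgfrb, with up to 17 M counts, exceeded the lowest non-tumor total of 14.9 M.

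The effect of BrM differed between groups by tests of the difference itself. Between lung and breast BrM 317 genes differed in the CD31 sort and 931 in the PDGFRb sort, and 1849 genes had different BrM effects in the 2 sorts (745 with the mouse as a block). The PDGFRb effect minus the CD31 effect was -3.04 for Cldn5, -3.31 for Mfsd2a, -4.37 for Angpt2 and 2.55 for Vcam1 on the log2 scale. For Cd276 it was -7.36, resting on 1 non-tumor count. Vcam1 was 5 log2 units higher in lung than breast BrM in the PDGFRb sort. The interferon list's median log2 difference, lung minus breast, was -1.96 in the CD31 and -3.17 in the PDGFRb sort.

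The rises in the CD31 sort of BrM could come from carried-over cancer RNA, from dates or from endothelial cells. Carry-over stays open in both origins. Its estimate was under 50% of the rise for 40.2% (1114 of 2772) of the rises in breast and 82.9% (2514 of 3032) in lung BrM, and for 20 of 34 and 33 of 33 proliferation genes, under an assumed composition. The median rise varied 1.28-fold between breast mice, where epithelial RNA varied 21.6-fold, but these genes were called partly for low spread, and the proliferation genes varied 2.33-fold in the order of epithelial RNA. In lung BrM these values were 1.6-fold and 2.8-fold, but epithelial genes did not follow each other (3.27-fold), so the test is void there. Slopes and a control on summed CPM, which lung BrM passed, were tried and dropped. Dates cannot be the whole cause, since the median log2 rise was 1.54 with the date in the fit and 1.62 without. For Cd276 the source stays open. Carry-over estimates were 18.8% of the level in lung BrM (2.42% to 148%, 4 mice) and 282% in breast BrM (24% to 593%, 4 mice).

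The lower interferon response in CD31 lung than breast BrM may reflect endothelium or cancer cell RNA, and the lines also differ in untested ways. Non-tumor libraries of a lung date were 0.23 log2 CPM (edgeR) above those of breast dates (2 each, SD 0.19). Lung minus breast BrM was -2.3. This argues against dates for 2 of 5 lung libraries, but other lung dates had no controls. Carried-over breast cancer RNA stays open. Excess over lung BrM was 2.26-fold higher in the breast library with the most than the least epithelial RNA. An inducible list can vary in such RNA. Such RNA cannot put lung BrM (4.91) below non-tumor brain (6.76 log2(CPM + 1)). Dilution is excluded, as the endothelial core list differed by a median of 0.08 ± 0.082 (SE) and the interferon list by -1.96.

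Other splits of the same libraries tested whether chance alone gives as many called genes. In the CD31 sort the real split called 5696 genes in BrM, 4473 in breast BrM, 5182 in lung BrM and 317 between the origins, and the highest other of 100 splits each called 0, 0, 172 and 195. The 0 are edgeR calls, not counts at an unadjusted p. In the PDGFRb sort it called 2986, 1531, 2977 and 931, and the highest others called 1004, 637 and 899 of 100 splits and 359 of all 35 splits. For the difference between sorts it called 1849 against 1 in 100 splits. In each case only the real split, 1, called as many genes, so chance can be excluded for these counts, while the split by origin also follows the dates, and with the date in the fit edgeR called 0 genes between the origins in the CD31 sort (955 at an unadjusted p under 0.05, 1 by limma-voom) and 102 in the PDGFRb sort. In non-tumor brain the sorts differed in 5173 genes against at most 85 in other splits, which argues against chance. The 16 parting every pair (others at most 69) are too few alone. At the preset correlation 18 lists were called in the CD31 and 24 in the PDGFRb sort. In each, 2 of 100 splits, the real one included, called as many, and the highest others called 19 and 25. Other CD31 splits called 1 to 19 lists and 0 genes, so chance is not excluded for a single list. With an estimated correlation 0 lists were called in either sort.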

How the results depend on the processing

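The fits with the date, with Y-linked reads, without low-Pdgfrb lung libraries and without genes open to carry-over were chosen after the data were seen. Over 289 gene results, 9434 values under the alternatives gave 8853 on the same side of the threshold, 557 weaker, 19 stronger and 5 reversed. 284 of these results were never reversed, and 134 moved by over 1.5 times without 1 library, 28 of them without the lung PDGFRb library of mouse 51435. Of 389 counts, 303 lay within 1.5 times the reported count, 25 were higher and 61 lower. Where no cause is given below, the cause was not tested.

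With RLE or upper-quartile scaling, no filter, the 1 CPM filter or the deposited log2 values, every count of called genes stayed within 1.5 times. DESeq2 called 872 genes between lung and breast BrM in the CD31 sort, and 3137 in breast BrM, 4483 in lung BrM and 2314 between the origins in the PDGFRb sort. Limma-voom called 490 between the origins in the CD31 sort and 1548 in the PDGFRb sort. On FPKM values the latter count was 1735 with a pseudocount of 1, 1469 with 0.1 and 1840 at a mean FPKM of at least 1, where 2304 genes were called in breast BrM. An absolute log2 change of at least 1 left 3590 genes in BrM in the CD31 sort, by construction.

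Fits of only the groups compared called 7117 genes in breast BrM and 122 between the origins in the CD31 sort, and 934 in breast BrM, 6676 in lung BrM and 437 between the origins in the PDGFRb sort. All libraries in 1 fit gave 3471, 2611 and 3107 genes in BrM, breast BrM and lung BrM in the CD31 sort, and 4557, 3136, 4554 and, between the origins, 2469 in the PDGFRb sort.

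Placing mouse 54135 by its cell type label mixed both sorts in non-tumor brain. Counts became 3623, 2390, 3000 and 63 for BrM, breast BrM, lung BrM and the origins in the CD31 sort, 1859, 644, 1816 and 426 in the PDGFRb sort, and 255 for the difference. Between sorts edgeR called 0, with 1732 at an unadjusted p under 0.05 and 6 by limma-voom. The 5 reversed values are Cldn5 in BrM in the CD31 sort (0.04), Dlx6os1 between sorts (-0.45), and Cd276 (0.16), Gbp4 (-0.22) and Birc5 (0.05) in the difference. Without mouse 54135 breast BrM gave 921 genes in the PDGFRb sort and the difference 1198. Without the lung mice with 2 numbers the origins gave 529 genes in the CD31 sort, and BrM, breast BrM, lung BrM and the origins 1347, 990, 752 and 120 in the PDGFRb sort. With the mouse as a block in edgeR the comparison of sorts gave 3885 genes and the difference 745, and with limma-voom's random effect 5752 and 2558.

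With the date in the fit, which takes the spread between dates from each group, BrM, breast BrM, lung BrM and the origins gave 3772, 2291, 1458 and 0 genes in the CD31 sort (edgeR, 955 at an unadjusted p under 0.05, 1 by limma-voom) and 1132, 115, 578 and 102 in the PDGFRb sort. Y-linked reads in the fit gave 1950 genes in BrM and 983 in breast BrM in the PDGFRb sort. Without the lung PDGFRb libraries with low Pdgfrb, BrM, breast BrM, lung BrM and the origins gave 458, 940, 161 and 26 genes and the difference 717, with the lone lung library assumed to vary like the other groups. Without genes whose carry-over share reached 50% of the level 138 genes differed between the origins in the CD31 sort.

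Leaving out 1 library gave 4715 to 7170 genes in BrM, 3726 to 6089 in breast BrM, 4287 to 6239 in lung BrM and 199 (without breast 53072) to 484 (without lung 56195-56520) between the origins in the CD31 sort. In the PDGFRb sort it gave 1875 to 6317, 830 to 3289, 1801 to 6961 and 349 to 2688, each highest without breast 51950. The comparison of sorts gave 4486 to 7061 and the difference 1390 to 3054, the highest without PDGFRb breast 51950. Called list members in BrM numbered 306 to 376 in the CD31 sort and 164 to 303 in the PDGFRb sort.

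Of the 18 CD31 and 24 PDGFRb lists called by camera in BrM, an estimated correlation kept 0 and 0, fry 18 and 13. Over all lists fry called 21 and 14 (mixed test 31 in CD31). With the controls split, breast and lung BrM shared 1789 calls in the CD31 sort, against 3439, and 191 in the PDGFRb sort, against 940. Each comparison then had fewer controls, and the genes tested differed too. Depth limits genes near 3 counts, at 0.125 to 0.422 CPM. Simulated 2-fold and 4-fold changes were called in 6% and 18% of PDGFRb and 32% and 78% of CD31 cases. Depth was not varied.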

Other observations

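The carry-over share and the search for Y-linked reads were chosen after the data were seen, and the correlation of lists was not. Respiratory chain genes and immediate early genes also changed in the CD31 sort of BrM. Genes of oxidative phosphorylation rose in 19 of 30 cases, 20 adjusted over the list alone (camera adjusted p = 0.0028, adjusted p = 0.41 with an estimated correlation), by small amounts. Cox8a, a subunit of cytochrome c oxidase, rose 2.07-fold from 162 ± 27.8 CPM in non-tumor brain to 338 ± 68.1 in breast and 332 ± 80.5 in lung BrM (n = 5 each), with a carry-over share of 77% of the level and 147% of the rise. Immediate early and heat shock genes fell in 13 of 21 cases, with 1 up and 13 down adjusted over the list alone (camera adjusted p = 0.0051, adjusted p = 0.53 with an estimated correlation). Hspa1a, a stress chaperone with a near copy in Hspa1b, fell 5.93-fold from 458 ± 311 CPM. In the PDGFRb sort of breast BrM lactate dehydrogenase A (Ldha) rose 4.68-fold from 543 ± 64.8 CPM (n = 5) to 2543 ± 707 (n = 4).

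The hypothesis was that mice with more dividing endothelial cells in BrM have more tip cell RNA. Over the 10 CD31 libraries of BrM the list levels had a Pearson r of 0.01 and a Spearman correlation of -0.07 (p = 0.98 and 0.87 from 1e+05 permutations). The r was -0.36 without the 2 libraries farthest from the median and -0.26 for deviations from origin means, so the lists did not rise together. Carry-over in the proliferation list leaves the hypothesis open. Reads of Y-linked genes were present in 3 mice, 2 non-tumor and 1 lung.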
